A study of Mus musculus with 4 samples.

How the data were processed

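RNA from 4 untreated mouse tumours was sequenced as polyA libraries. Per the labels, the tumours arose from neural stem cells with PDGF and the K27M mutation, total RNA was made into libraries with a TruSeq RNA kit that does not mark strand, and sequencing was on a HiSeq2500. The deposited table holds whole-number read counts per gene for the 4 tumours, and the authors made it with STAR and featureCounts on mm10, per the submitters' processing notes. Versions, strand setting and the handling of reads with several matches are not given in the sources used here. Genes follow the GENCODE vM8 annotation named with the table. The table held 46946 genes on 21 chromosomes and no mitochondrial gene. Symbols came from a table of gene identifiers and matched 46451 of them. Where 2 identifiers carried the same symbol, the one with more counts was used.

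The columns are called T14, T10, T8 and TUN. They match none of the sample titles one to one, so each was used as a tumour of the group PDGFB K27M with no replicate number. All 4 columns were used, with 0 columns of sample values left aside. The labels give a single group and no untreated brain, cultured cells or second genotype, so no test between groups was made. Nothing in the labels says more than that these are separate tumours, so p-values of the goodness of fit measure only the spread between these samples. Tests over genes, lists or gene sets compare genes with other genes and are no evidence from replicate tumours.

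Library totals were 23194257 counts for T14, 24369339 for T10, 24155724 for T8 and 21664889 for TUN. Counts were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3 (factors 0.971, 1.01, 0.988 and 1.03) and expressed as CPM, a count scaled to library size, or, with the merged exon length of the deposited table, as RPKM, which is also scaled to length. A count of 0 in a library allows up to 3 counts, which is 0.133 CPM in T14, 0.122 in T10, 0.126 in T8 and 0.134 in TUN. Such floors cover counting error only, since reads carried no molecular identifiers. A gene was detected where its CPM was 1 or more in all 4 tumours.

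Genes more variable between tumours than genes of like abundance were sought with an intercept-only edgeR model at the trended dispersion, after its default filter on low counts. The residual deviance was compared with a chi-square distribution with 3 degrees of freedom and adjusted by the Benjamini-Hochberg method over 14266 genes. With 1 group, the filter kept only genes above its low-count limit in all 4 tumours. Genes very low in even 1 library were therefore not tested, however high they were elsewhere. An example, chosen after its values were seen, is Cbln3, at 747 CPM in T14, 99.9 in T10, 6.16 in T8 and 0.357 in TUN. On simulated data with changes in 1 library the step recovered 0% of genes changed 2-fold, 14% of those changed 4-fold, 80% at 8-fold and 100% at 16-fold, with 3 calls among 14066 unchanged genes.

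A total of 34 gene lists were fixed before the data were examined, covering Polycomb, cell cycle, growth factor, lineage, immune, vascular, regional and control genes. For each list, the log2 CPM (prior count 2) of members at mean CPM 1 or more was centred on the 4-tumour mean and averaged per library. The SD of these 4 values was compared with 10000 random lists matched on abundance in 20 bins, adjusted over 29 lists. The 5 lists with fewer than 3 such members were the T and NK cell, B cell, neutrophil, control and sex-linked lists. In simulations 6.5% of unshifted lists and 96% of lists shifted by 1 log2 unit passed an unadjusted 0.05. The deviations of each gene were shuffled separately there, so these rates do not cover genes that vary together, as genes of a list can. Levels of 13 pairs of lists were compared by two-sided permutation tests over genes of the mean log2(RPKM + 0.1), with 100000 resamples or exact enumeration, adjusted over the 13. In simulations of this step, 6% of unshifted and 96% of pairs shifted by 3 log2 units passed. Genes are not independent replicates, so these tests describe the genes of a list and not the animals. Ratios of 10 pairs of genes used the same scale and a two-sided exact sign-flip test, which cannot pass the threshold of 0.05 with 4 tumours, so no ratio can be called. Values far from the other libraries were sought with Dixon's ratio (critical value 0.829).

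Named genes followed a rule set before the data were examined. It took the members of the PRC2, demethylase and CDK inhibitor lists with the genes of the ratios and Pdgfb, Pdgfra, Ezh2 and Cdkn2a. Its wording also allowed a narrower reading, in which only members that occur in a ratio are taken, and the wider one was used. It took the 3 most abundant members of each other list with up to 4 members past the goodness of fit, and the 10 most abundant genes. It also took the 20 smallest goodness-of-fit p-values and, per tumour, the 5 genes with the largest gap to the nearest other tumour, in both cases at mean CPM 5 or more. Some genes that the rule takes are not reported here. Other names are marked in the text as chosen after their values were seen. Each alternative changed 1 choice, among DESeq2 1.42.0 size factors, no scaling beyond the total, other detection thresholds and filters, a common dispersion, DESeq2 dispersion outliers, CPM in place of RPKM, pseudocount 1, prior count 0.5, list medians, and leaving out each tumour. A further 7 lists of synaptic, brainstem, cerebellar, cortical, striatal, choroid plexus and pituitary genes were written after the fixed lists had been read and before their own values were. The exceptions were Prl and Gh of the pituitary list, already seen as control genes. The share of brainstem or cerebellar genes highest in a library was compared with that of the synaptic, cortical and striatal genes by a Fisher exact test over genes, added after the values were seen. Shifts of whole chromosomes, from genes at mean CPM 5 or more, were compared with 10000 random gene sets matched on abundance, adjusted over 80 tests. In simulations of that step 7% of unshifted sets and 100% of sets shifted by 0.25 passed. A correction for gene length and GC content used quadratic trends per library, with GC values from GENCODE vM21 transcripts for 99.8% of genes. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.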

Results

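The transcriptomes of 4 mouse tumours were profiled by polyA RNA sequencing. The sample labels describe untreated tumours grown from neural stem cells that carry PDGF and the K27M mutation, which replaces lysine 27 of histone H3 and blocks its methylation by the PRC2 complex. The text for the series as a whole describes instead tumours from injected DIPG cells (diffuse intrinsic pontine glioma) with mutant histone H3.3, and the tables used here do not settle this difference. All 4 tumours form 1 group. The title of the series concerns EZH2, the main methyltransferase of PRC2, as a target in such gliomas, so the values below give the level of Polycomb, cell cycle and lineage genes in each tumour and their spread. The libraries are named T14, T10, T8 and TUN as in the deposited table. They held between 21664889 and 24369339 counts.

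The most abundant gene was Olig1, a transcription factor of the oligodendrocyte lineage, at 3014 ± 668 CPM (SD, n = 4). Among the 10 most abundant genes were also Ptprz1 (2615 ± 311 CPM), Pdgfra (2182 ± 770 CPM), the cyclin gene Ccnd1 (2721 ± 518 CPM), Serpine2 (2323 ± 248 CPM) and Gpm6b (2246 ± 406 CPM). The others were Eef2, Scd2, Eef1a1 and Hsp90ab1. The 10 most abundant genes of each library took 2.34% to 3.28% of its counts. CPM of 1 or more in all 4 tumours was reached by 13245 genes. The biological coefficient of variation was 37.6%. T8 and TUN differed over 2-fold at 651 genes and T14 and T10 at 694, while the other pairs of libraries differed at 2214 to 2585 genes.

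Ezh2 (ENSMUSG00000029687.16, chromosome 6, 47530139 to 47595341 in mm10) was expressed in every tumour, at 44.5 CPM in T14, 47.6 in T10, 87.2 in T8 and 101 in TUN. Its paralog Ezh1, which is known for expression in non-dividing cells, ran the other way, with 61.3, 41.2, 17.4 and 18.7 CPM in the same order. The log2 ratio of Ezh2 to Ezh1 was -0.30 in T14, 0.36 in T10, 2.44 in T8 and 2.54 in TUN, a mean of 1.26 ± 1.45 (SD, n = 4), positive in 3 of 4 tumours (exact sign-flip p = 0.25). T14 and T10, with the lower ratios, also had lower mitosis genes and higher neuron and astrocyte genes, as described below. Bulk counts cannot tell whether the ratio differed within tumour cells or with the mix of cells in a library. The other core subunits stood at 28.1 ± 6.2 CPM (Eed) and 101 ± 13 CPM (Suz12), and the accessory subunits at 71.8 ± 7.54 CPM (Jarid2), 99.5 ± 9.71 CPM (Aebp2), 31.3 ± 4.3 CPM (Mtf2) and 27.6 ± 10.5 CPM (Phf19). All 11 PRC2 genes and all 20 PRC1 genes were detected in all 4 tumours. PRC2 genes stood 0.35 log2 units above PRC1 genes, a difference that did not pass the permutation test over genes (adjusted p = 0.548, same direction in 4 of 4 tumours).

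No PRC2 gene was more variable than the trend in edgeR, over all genes tested or adjusted over the list alone. The list as a whole did not pass the test against random lists (adjusted p = 0.857). Neither result shows that PRC2 genes were stable. Ezh2 spanned 2.26-fold and Ezh1 3.53-fold between libraries. In simulations the goodness of fit recovered 0% of genes changed 2-fold and 14% of those changed 4-fold. In the list mean Ezh2 and Ezh1, which ran opposite ways, offset each other. The same limit of the goodness of fit holds for the other lists in which no gene passed. Of the 20 PRC1 genes only Cbx7 passed (adjusted p = 0.0365; 1 adjusted over the list alone), at 45.3 CPM in T14, 28 in T10, 7 in T8 and 9.02 in TUN. The H3K27 demethylase genes stood at 64 ± 5.53 CPM (Kdm6a) and 75.8 ± 8.38 CPM (Kdm6b). Their log2 ratio was -0.47 ± 0.24 and below 0 in 4 of 4 tumours. Without length correction the mean was -0.24 and the ratio was above 0 in T14, so the direction in T14 depends on gene length. The exact sign-flip test gives no call either way. Of the genes for histone H3.3, H3f3b stood at 539 ± 168 CPM and H3f3a at 44.7 ± 7.13 CPM, a log2 ratio of H3f3a to H3f3b of -3.775 ± 0.325. Processed copies of H3f3a in the genome can share its reads, so its level is uncertain. If the tumours carry an introduced H3.3 sequence, gene counts do not separate it from the mouse genes. The chaperone genes stood at 288 ± 33.4 CPM (Atrx), 40.6 ± 4.94 CPM (Daxx) and 26.4 ± 3.92 CPM (Hira), and the list of demethylase and H3.3 genes did not pass the test against random lists (adjusted p = 0.44). None of its 11 genes passed the goodness of fit, over all genes or adjusted over the list alone.

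Pdgfb (ENSMUSG00000000489.6, chromosome 15, 79995900 to 80014808) reached 1499 CPM in T14, 922 in T10, 1330 in T8 and 2461 in TUN. Gene counts do not separate an introduced PDGFB sequence from the mouse gene. The related ligand gene Pdgfa stood at 19.6 ± 2.76 CPM, a log2 ratio of Pdgfb to Pdgfa of 6.30 ± 0.67 (SD, n = 4). The receptor gene Pdgfra exceeded Pdgfrb (48.1 ± 6.67 CPM) by 4.55 ± 0.67 log2 units. Both ratios were above 0 in 4 of 4 tumours, the most the exact sign-flip test can use. Of the 18 PDGF and receptor tyrosine kinase genes, only Fgfr2 was more variable than the trend in edgeR (adjusted p = 0.0012), at 49.6 CPM in T14, 37.1 in T10, 9.26 in T8 and 4.33 in TUN. Adjusted over the list alone, 2 of them passed.

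Cdkn2a (ENSMUSG00000044303.6, chromosome 4, 89274471 to 89294653), which encodes the p16 and p19Arf inhibitors of proliferation, was detected in all tumours at 14.2 CPM in T14, 7.9 in T10, 15.3 in T8 and 23.8 in TUN. Gene counts do not separate its 2 products. It stood below Cdkn2c by 1.88 ± 0.31 log2 units and below Cdkn1a by 1.86 ± 0.15 (SD, n = 4). Cdkn2b stood at 59.5 ± 32.8 CPM, Cdkn1b at 210 ± 34.4 CPM and Trp53 at 73.6 ± 27.5 CPM. Cdk4 stood at 385 ± 147 CPM and Cdk6 at 5.25 ± 0.993 CPM, a log2 ratio of 7.89 ± 0.72. Without length correction these 3 ratios were -3.08, -2.78 and 6.10. None of the 17 CDK inhibitor and G1 genes passed the goodness of fit, over all genes or adjusted over the list alone. Their level exceeded that of the mitosis genes by 0.29 log2 units, which did not pass the permutation test over genes (adjusted p = 0.652, in 3 of 4 tumours).

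**Figure D1:**
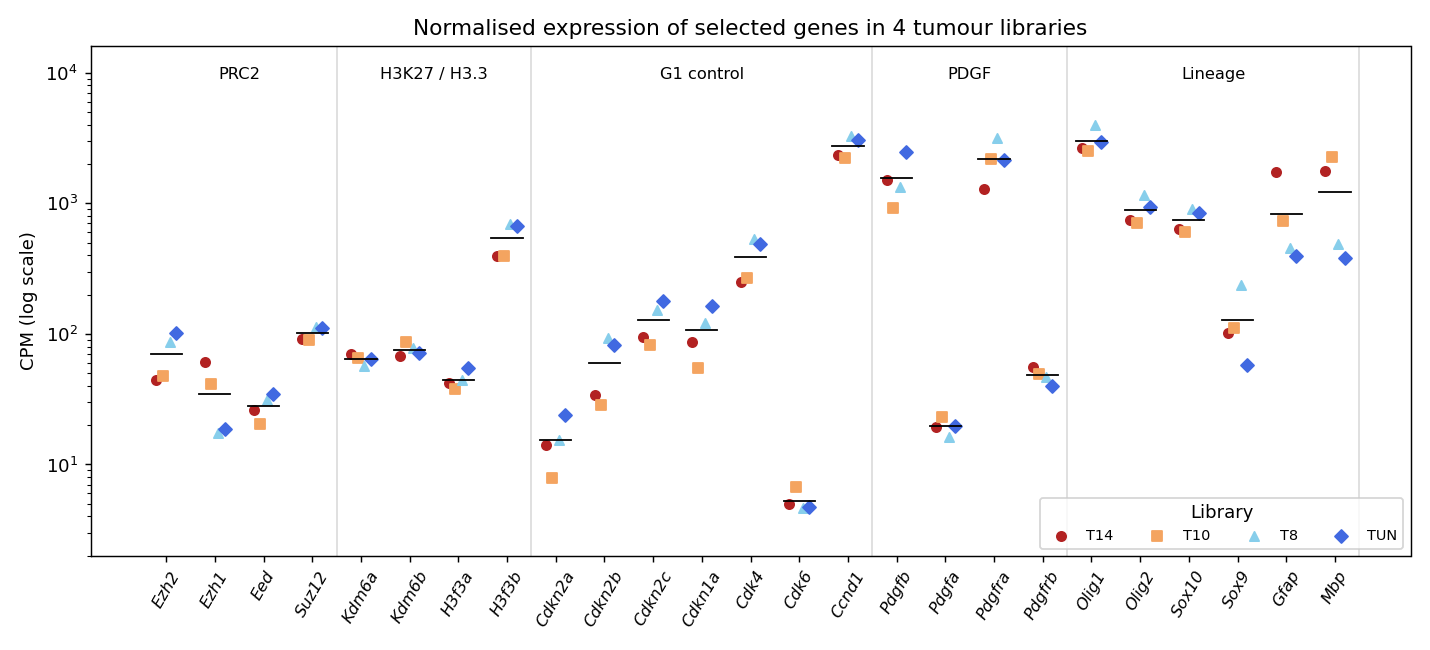
Normalised expression in CPM (log axis) of selected Polycomb, H3.3, G1 control, PDGF and lineage genes; each symbol is 1 of 4 tumour libraries and the black line is their mean. Ezh2 lies at 44.5 to 101 CPM, Pdgfb at 922 to 2461 CPM and Cdk6 at 4.61 to 6.72 CPM.

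The 19 oligodendrocyte precursor genes were detected in all 4 tumours, led by Olig1 (1394 ± 309 RPKM, n = 4), Lhfpl3 (381 ± 74.3 RPKM) and Olig2 (363 ± 83.6 RPKM). They stood above the mature oligodendrocyte genes by 2.42 log2 units, above the neuron genes by 2.65 and above the neural stem cell and radial glia genes by 2.08, each in 4 of 4 tumours (adjusted permutation p over genes 0.0078, 0.00113 and 0.0404). The difference from astrocyte genes was 1.08 and did not pass (adjusted permutation p = 0.202, in 3 of 4 tumours). The exception was T14, at -0.23, where the astrocyte gene Gfap reached 1719 CPM. Sox10 exceeded Sox9 by 3.32 ± 0.83 log2 units and Olig2 exceeded Gfap by 1.12 ± 1.21, in 4 of 4 and 3 of 4 tumours, without a call in the exact sign-flip test. Genes that mark the proneural class of glioma stood 2.12 log2 units above mesenchymal class genes in 4 of 4 tumours (adjusted permutation p = 0.00693). Neural stem cell genes were led by Fabp7 (728 ± 328 CPM), Vim (1523 ± 762 CPM) and Sox2 (241 ± 68.3 CPM).

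Genes of microglia, the resident immune cells of the brain, were present in every tumour. All 16 were detected, with C1qa at 159 ± 36.3 CPM and C1qb at 107 ± 31.5 CPM (SD, n = 4). Microglia genes stood 3.14 log2 units above macrophage and monocyte genes and 6.79 above T and NK cell genes, and macrophage genes stood 2.99 above neutrophil genes, each in 4 of 4 tumours (adjusted permutation p over genes 0.00426, 0.00026 and 0.00253). The T and NK cell and neutrophil lists lie near 0 counts, so the pseudocount sets the size of the last 2 differences, which were 4.04 and 1.47 with pseudocount 1. None of the 14 T and NK cell genes reached 1 CPM in all tumours. Cd3e and Cd3g, chosen after their values were seen, had 0 counts in every library. Of the B cell genes Cd22 alone was detected in all 4 tumours (3 ± 1.68 CPM), and the neutrophil genes S100a8 and S100a9 stood at 0.74 ± 0.38 and 0.73 ± 0.51 CPM. Of 10 macrophage genes tested, Lyz2 and Arg1 were more variable than the trend in edgeR (adjusted p = 0.000419 and 0.00279; 2 adjusted over the list alone), and of the 16 microglia genes 0 were. Lyz2 stood at 195 CPM in T14, 113 in T10, 337 in T8 and 951 in TUN, and Arg1 at 3.11, 0.57, 7.96 and 18.8 CPM. As a whole neither microglia (adjusted p = 0.651) nor macrophage genes (adjusted p = 0.201) passed the test against random lists. Macrophage genes passed without T14 (adjusted p = 0.0178).

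Between tumours, 10 of the 29 lists tested varied more than random lists. Mitosis genes deviated from their 4-tumour mean by -0.50 log2 units in T14, -0.65 in T10, 0.40 in T8 and 0.74 in TUN, and all 21 were highest in TUN. Top2a, the topoisomerase of dividing cells, stood at 276, 278, 500 and 677 CPM in that order, and Cdc20 at 47.1, 36.4, 93.7 and 110 CPM. S-phase genes deviated by -0.73, -0.38, 0.47 and 0.63, with Rrm2 at 101, 102, 259 and 280 CPM. Both lists had an adjusted p of 0.000483 against random lists, which corresponds to the smallest p that 10000 random lists can give, 1e-04. No single gene of either list passed the edgeR goodness of fit, over all genes or adjusted over the list alone.

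Neuron genes deviated by 1.31 log2 units in T14, 1.27 in T10, -1.02 in T8 and -1.55 in TUN (adjusted p = 0.000483), and 13 of 17 passed the edgeR goodness of fit (13 adjusted over the list alone). Snap25, a synaptic vesicle fusion gene, stood at 1580, 1329, 124 and 63.8 CPM. Rbfox3, which encodes the neuronal antigen NeuN, stood at 119, 58.3, 3.39 and 2.23 CPM. Astrocyte genes deviated by 1.16, 0.65, -0.81 and -0.999, and 9 of 16 passed (13 adjusted over the list alone), among them Aldoc at 1432, 907, 243 and 265 CPM and Gja1 at 209, 165, 27.4 and 28.5 CPM. Mature oligodendrocyte genes deviated by 0.50, 1.03, -0.76 and -0.76, and 8 of 16 passed (10 adjusted over the list alone), among them Mal at 98.2, 138, 18.8 and 16.4 CPM. The myelin gene Mbp stood at 1764, 2268, 486 and 379 CPM. Both lists also had an adjusted p of 0.000483. Oligodendrocyte precursor genes, by contrast, deviated by -0.16, 0.04, 0.09 and 0.03 (adjusted p = 0.494), and none of the 19 passed the goodness of fit, over all genes or adjusted over the list alone.

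**Figure D2:**
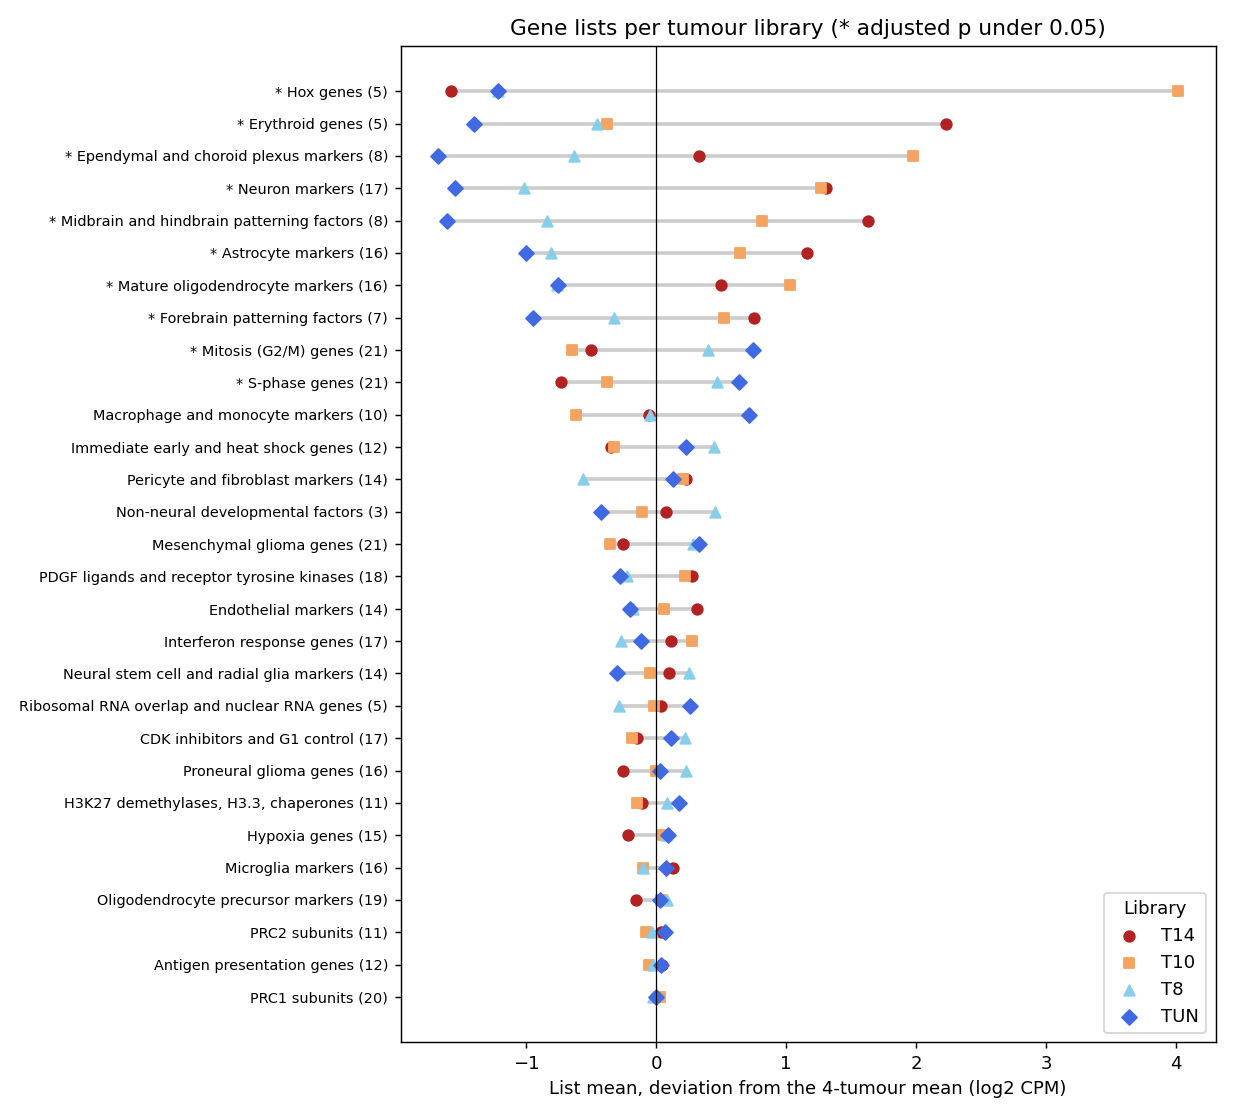
Mean deviation of each tested gene list from its 4-tumour mean (log2 CPM) in each tumour library, with the number of members used in brackets; symbols are single libraries, grey lines span them and asterisks mark an adjusted p under 0.05. Neuron genes range from -1.55 in TUN to 1.31 in T14 and Hox genes reach 4.02 in T10.

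Regional genes also differed. Hox genes, which set position along the hindbrain and spinal cord, were near the floor in most libraries, and at CPM 1 or more stood 12 of 23 genes of paralog groups 1 to 8 in T10 against 1 in T14 and 0 in T8 and TUN. Hoxb5 (chromosome 11, 96303336 to 96306121) had 379 counts in T10 (15.4 CPM) and 1, 4 and 1 counts in T14, T8 and TUN. Hoxa5 (chromosome 6, 52201754 to 52204587) had 302 counts in T10 (12.3 CPM) and 2, 3 and 1 in the others. Hoxb5 overlaps an antisense gene whose reads cannot be told apart from its own. The Hox list deviated by 4.02 log2 units in T10 over 5 members (adjusted p = 0.000483), but these reached mean CPM 1 only through T10. Over all 23 Hox genes with a count, a setting added after seeing the data, the deviations were -0.81 in T14, 2.20 in T10, -0.56 in T8 and -0.82 in TUN (adjusted p = 0.000425). No Hox gene passed the low-count filter, so 0 were tested one by one. Hox genes as a whole stood 2.20 log2 units below forebrain factors (adjusted permutation p = 0.00104, 4 of 4 tumours; 1.04 below with pseudocount 1 and 3.16 below in CPM, since most Hox genes lie near 0 counts) and 0.32 below liver, muscle and endocrine control genes (adjusted permutation p = 0.295). Without T10 the latter difference was -0.72 and passed (adjusted permutation p = 0.0139). Non-neural developmental factors, targets of Polycomb in stem cells, lay -0.13 log2 units from the same control genes (adjusted permutation p = 0.734), and in CPM this turned to 0.49.

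Midbrain and hindbrain factors deviated by 1.63 log2 units in T14, 0.82 in T10, -0.84 in T8 and -1.61 in TUN (adjusted p = 0.000725). The midbrain and hindbrain factor En2 stood at 83.7, 8.75, 0.712 and 0.581 CPM. Forebrain factors deviated by 0.75, 0.52, -0.33 and -0.95 (adjusted p = 0.0299), with Zic1 at 390, 104, 13.9 and 6.97 CPM. This call was lost without TUN (adjusted p = 0.16), with members at mean CPM 5 or more (adjusted p = 0.199) and with all members that had a count (adjusted p = 0.141). Ependymal and choroid plexus genes deviated by 0.33, 1.98, -0.63 and -1.68 (adjusted p = 0.000725), with Ttr, the transthyretin gene of the choroid plexus, at 34, 579, 36.9 and 3.35 CPM. Erythroid genes deviated by 2.23, -0.38, -0.45 and -1.40 over 5 members, all highest in T14 (adjusted p = 0.0029), with Hbb-bs at 56.5, 7.57, 6.83 and 3.22 CPM. Since T14 partly decided which erythroid genes reached mean CPM 1, all 10 were also used, in the same added setting, and deviated by 1.56, -0.32, -0.40 and -0.85 (adjusted p = 0.00113). Adjusted over the list alone, the goodness of fit called 1 of 5 tested genes of the midbrain and hindbrain list, 1 of 5 of the forebrain list, 3 of 5 of the ependymal list and 3 of 3 of the erythroid list, against 1, 1, 2 and 2 over all genes. The globin genes share reads between near-identical copies.

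**Figure D3:**
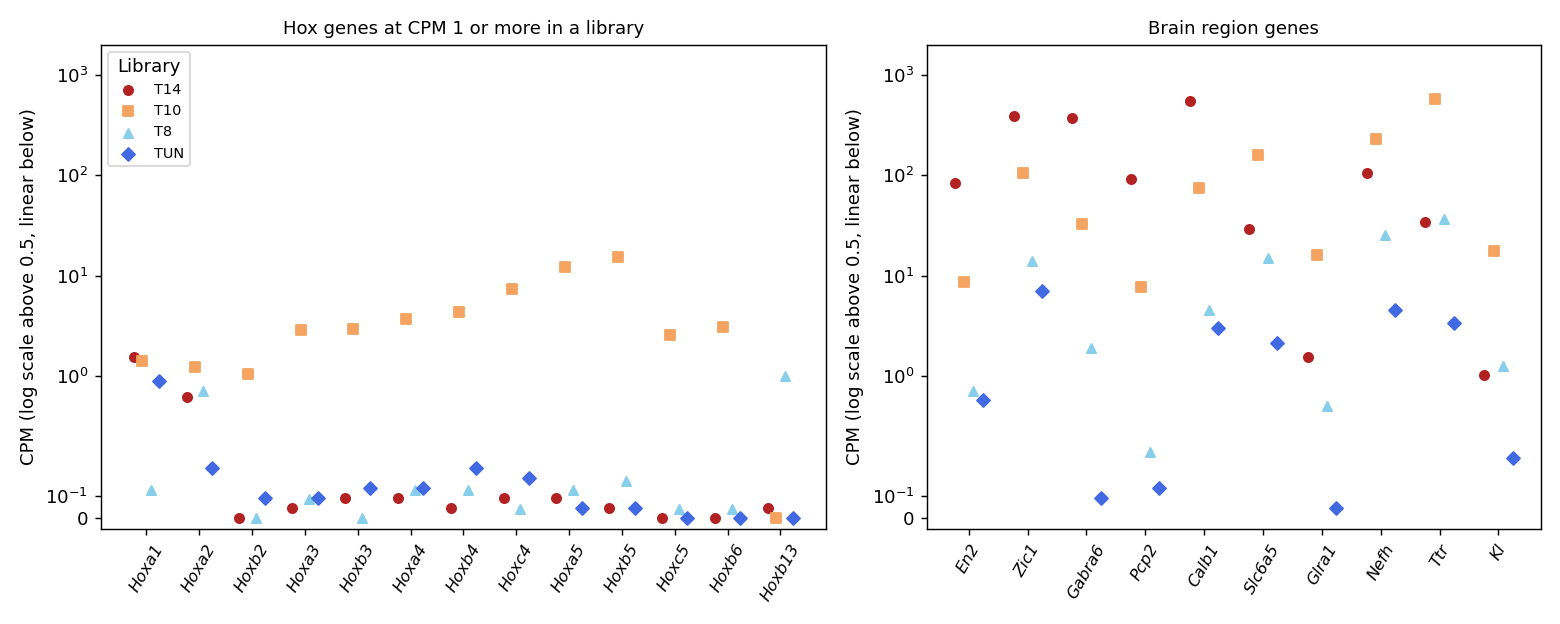
Expression in CPM (log axis above 0.5, linear below) of the Hox genes that reach 1 CPM in a library (left) and of genes of brain regions (right), the latter partly chosen after their values were seen; each symbol is 1 tumour library. Hoxb5 lies at 15.4 CPM in T10, and En2 ranges from 83.7 CPM in T14 to 0.581 in TUN.

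The edgeR goodness of fit called 619 of 14266 genes (4.34%), and 1196 had an unadjusted p under 0.05. As dispersion outliers in DESeq2, 78 genes were called, all among the 619. Of the 619, 426 were highest in T14, 153 in T10, 21 in T8 and 19 in TUN, and 391 were lowest in TUN. For 566 of them (91.4%) T14 and T10 were the 2 highest libraries, as for the neuron, astrocyte and mature oligodendrocyte lists. Cbx7 and Fgfr2 had the same 2 highest libraries, so their calls are not particular to Polycomb or PDGF genes. Genes very low in any library had been filtered out and are not among these. Among the genes tested, the smallest adjusted p was that of Rgs8 (1.04e-27), at 687 CPM in T14, 64 in T10, 6.83 in T8 and 2.41 in TUN. It was followed by the calcium-binding gene Calb1 (547, 74.2, 4.53 and 2.99 CPM, adjusted p = 1.79e-25). Car9, the hypoxia-regulated carbonic anhydrase gene (chromosome 4, 43506966 to 43513729), stood at 147 CPM in T10 against 2.57 in T14, 1.43 in T8 and 0.982 in TUN (adjusted p = 4.61e-24). The gene overlaps Gm12454. Fat2, Grm4, Camk4 and Gdf10, among the other 20 smallest, were highest in T14. Among the called genes, the largest gaps in T8 were low values of Ndst3, Cacna1g, Cadps2 and March1 and a high value of Pcdhgb6 (52.6 CPM against 7.28, 3.42 and 2.41). In TUN they were low values of St6gal2 (0.714 CPM), Ttr, Sox1 (0.625 CPM), Cntnap5b and Pvalb.

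The other lists did not pass the test against random lists when members were averaged. Their adjusted p-values were 0.146 for pericyte and fibroblast, mesenchymal glioma and immediate early genes, 0.201 for PDGF genes, 0.216 for proneural genes, 0.253 for neural stem cell genes and 0.313 for CDK inhibitor genes. They were 0.403 for endothelial, 0.494 for hypoxia, 0.522 for nuclear RNA, 0.663 for non-neural factor, 0.692 for interferon response and 0.981 for PRC1 and antigen presentation genes. Pericyte and mesenchymal genes passed without T14 (adjusted p = 0.0317 and 0.0394). Without T8 the SD of the pericyte list fell from 0.377 to 0.0389 (adjusted p = 0.93 against random lists), so its spread came from T8. With list medians in place of means, 7 of these lists passed: mesenchymal (adjusted p = 0.00145), hypoxia (0.0029), immediate early (0.00507), CDK inhibitor (0.00691), pericyte (0.0143), PDGF (0.0153) and neural stem cell genes (0.0228). The goodness of fit called 1 gene each of the neural stem cell (Sox1, of 14), endothelial (Slco1a4, of 14), hypoxia (Car9, of 15) and nuclear RNA lists (Neat1, of 5), with the same counts adjusted over the list alone. It called 0 of 14 pericyte, 16 proneural, 21 mesenchymal, 17 interferon, 12 antigen presentation, 13 immediate early and 2 non-neural factor genes either way, and 0 of the 1 B cell gene tested. No T and NK cell, neutrophil or control gene was tested. Of the sex-linked genes Xist alone was tested, so its list leaves the p-value unadjusted. That unadjusted p was under 0.05 in the goodness of fit, and Xist did not pass when adjusted over all genes. The hypoxia genes Ldha and Pgk1 stood at 411 ± 211 and 368 ± 141 CPM, the interferon gene Ifit2 at 85.3 ± 9.43 CPM and the antigen presentation gene B2m at 200 ± 26.5 CPM (SD, n = 4). The nuclear RNA Neat1 stood at 160 CPM in TUN against 34.9, 43.5 and 18.7 in T14, T10 and T8 (edgeR adjusted p = 0.000567). Xist, the RNA of the inactive X chromosome, stood at 577 ± 283 CPM and was present in every library, while the Y-linked Ddx3y and Uty, chosen after their values were seen, had 0 counts in each. The control genes of liver and muscle stayed near the floor, with Acta1 at 0.41 ± 0.35 CPM and Apoa2 at 0.43 ± 0.23 CPM.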

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

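The test of general Polycomb loss below and the comparison with other neuronal lists were chosen after their results were seen, and the marker lists were written after the Hox values were seen and before their own. Of 204 values examined, 8 had a library far from the other 3, and about 10 would be expected by chance. Hox genes deviated by 4.02 log2 units in T10 over 5 members that reached mean CPM 1 only through T10, and by 2.20 over all 23 with a count. The single values of Hoxa5 (12.3 CPM) and Hoxb5 (15.4 CPM) stood apart there. For a general loss of Polycomb repression, 0 of 16 Hox genes of paralog groups 9 to 13 reached 1 CPM in T10. Non-neural factors did so no more often in T10 (2 of 18) than in T14 (3) or TUN (3). T10 therefore showed no wider gain of these genes. This cannot decide whether repression was kept, since a gene can be silent for other reasons and every tumour here is labelled K27M. Still open is brainstem or spinal cord tissue in T10, which may bring its own Hox transcripts. Of its 20 markers, 16 reached 1 CPM in a library, and 14 of these (87.5%) were highest in T10. The share was 44.4% of 45 synaptic, cortical and striatal genes under the same limit (Fisher exact p = 0.00332 over genes, which are not independent). The markers were low, with a median of 4.74 CPM in T10 and 2.06 in T14. T10 itself may have brought some of them past the limit, which favours its share. Slc6a5, chosen after its value was seen, stood at 161 CPM in T10 against 29.4, 14.9 and 2.14 in T14, T8 and TUN. Also open is a tumour that itself kept such a regional identity, which was not tested, and the labels name no site of growth.

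The other values of this kind are given without explanation. Aebp2 stood at 114 CPM in T8, against 93.4 to 95.8 in the others. Gabra5 stood at 20.5 CPM in T10, against 1.29 to 1.72. Map2 stood at 1066 CPM in T10, against 742 to 777. Pericyte and fibroblast genes deviated by -0.56 log2 units in T8, and hypoxia genes by -0.22 in T14. The hypoxia value is a list mean that includes Car9, at 147 CPM in T10 against 2.57 in T14. Of the 15 hypoxia genes 7 were lowest in T10 and 4 in T14, so the low mean does not mark T14 gene by gene.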

How the results depend on the processing

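The correction for length and GC content, the use of all members with a count and the chromosome settings were chosen after seeing the data. Detected genes numbered 12339 to 14050 over all settings (13286 to 13443 leaving out a tumour at a time, 13310 without T14). Variable genes numbered 618 to 722 over edgeR settings and 426 to 462 leaving out a tumour, and 478 of the 619 were called with no filter. DESeq2 called 78 dispersion outliers, all among the 619; the cause was not tested. With list medians 17 lists varied together instead of 10; the cause was not tested. Leaving out a tumour gave 9 to 12 lists, and members at mean CPM 5 or more gave 7: Hox and erythroid genes then had too few members, and the forebrain list no longer passed. All members with a count gave 9, without the forebrain list. The Hox list had too few members without T10, as had the erythroid list without T14. Of 100 values of level differences under alternatives, 98 kept direction and side of the threshold. Hox against control genes ranged from -0.721 (without T10) to -0.151 leaving out a tumour and reached -0.0203 with list medians, and non-neural factors against control genes turned to 0.489 in CPM; the cause was not tested. Without length correction log2 ratios moved to -3.08 (Cdkn2a/Cdkn2c), -2.78 (Cdkn2a/Cdkn1a), 5.44 (Pdgfra/Pdgfrb) and 6.1 (Cdk4/Cdk6), and pseudocount 1 gave 6.36 for Cdk4/Cdk6. Olig2/Gfap was 0.33 without length correction, within its SD. Of 352 named genes, 27 were weaker without TUN, 22 without T14, 20 without T10 and 20 without T8.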

Other observations

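Tests of synaptic genes, of dilution, of cerebellar against other neuronal genes, and of differences along chromosome 14 (the first against the last of 3 equal gene groups, and windows of 10 Mb) were chosen after their results were seen. Genes first named in this part were chosen after their values were seen. The unnamed gene Gm35585 stood at 65.1 CPM in T8 and at or under 0.0447 CPM elsewhere. Hoxb13 had 24 counts in T8 and at most 1 elsewhere. Spp1 and Gpnmb, known in activated macrophages, were more variable than the trend (edgeR adjusted p = 0.00858 and 0.0376). Spp1 stood at 283 CPM in T14, 137 in T10, 683 in T8 and 848 in TUN, and Gpnmb at 62.5, 11.3, 54.7 and 80.2 CPM. The pituitary hormone gene Prl had 66 counts in T8, 15 in TUN and 0 in T14 and T10, and Gh had 17, 5, 1 and 0 counts in T8, TUN, T14 and T10. Of the 14 pituitary genes 4 reached 1 CPM in a library, 2 of them highest in T10.

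Markers of brain regions differed in their order between libraries. Choroid plexus genes outside the fixed list were highest in T10 for 12 of 16 (deviation 1.44 log2 units, adjusted p = 0.00015 over the 6 lists of this kind that could be tested). Cortical and hippocampal genes deviated by 0.57, 0.78, -0.63 and -0.72 in T14, T10, T8 and TUN (adjusted p = 0.00084) and striatal genes by 0.66, 0.81, -0.74 and -0.73 (adjusted p = 0.0021). Synaptic genes deviated by 1.39, 1.03, -1.09 and -1.33, brainstem and spinal cord genes by 0.10, 1.96, -0.44 and -1.62, and cerebellar genes by 3.48, 0.93, -1.47 and -2.93 (each with an adjusted p of 0.00015, from the smallest p random lists can give).

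Neuron, astrocyte and mature oligodendrocyte genes were highest in T14 and T10. Bias by transcript length and GC content is argued against, since 97.1% of the neuron list's spread stayed after its correction. Different amounts of non-tumour brain tissue stay open and undecided: the deviations of 20 synaptic genes outside the fixed list, a test that replaced an earlier one, had an SD of 1.41, but any source of neuronal transcripts would give this. In T14, cerebellar tissue may account for En2 and Zic1, since 100% of 20 cerebellar markers, such as Gabra6 (370 CPM) and Calb1 (547 CPM), were highest there, against 44.4% of 45 synaptic, cortical and striatal genes (Fisher exact p = 5.25e-06 over genes). Whether dilution by other tissue is the whole cause of the lower mitosis and S-phase values cannot be told apart from slower proliferation, since mitosis and precursor genes deviated differently (smallest adjusted permutation p = 2.67e-05) but ordinary brain tissue also expresses precursor genes, and for these lists no biological explanation was tested.

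Genes of chromosome 14 were lower in TUN, with a median shift of -0.479 log2 units over 408 genes, 80.1% of them below the library's median (adjusted p = 0.00229 against random gene sets). Bias by length and GC content (114% of the shift stayed after correction) and non-tumour tissue (101% stayed among the 204 genes that differ least between T14 and T8) are argued against, as is a lower dose of the whole chromosome, since the first and last of 3 equal gene groups differed by 0.593 (permutation p = 2e-05, the smallest these permutations can give). An earlier form of that test, on the weakest of the 3 groups (-0.107, -0.57 and -0.70), decided nothing and was replaced. A lower dose of the part beyond 40 Mb may account for the pattern: of windows with 20 or more genes, the 4 from 40 to 80 Mb shifted by -0.548 to -0.676 and the 3 before by 0.01 to -0.14, the 57 genes beyond 80 Mb shifted by -0.733, and no DNA was measured here. Of 80 pairs of chromosome and library 13 passed the threshold, 6 of them the opposite shifts that centring gives the other libraries for chromosome 14 and for chromosome 1, which was higher in T10 (0.25 over 710 genes, 0.156 to 0.546 in windows up to 160 Mb and 0.0419 to 0.106 in those beyond), and the largest of the rest was -0.128, for chromosome 18 in T10. After the length and GC correction the chromosome 1 shift in T10 fell from 0.252 to 0.188.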
